A study of Mus musculus with 38 samples.

How the data were processed

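RNA was sequenced from sorted mouse thymocytes, and the analysis started from the authors' processed files. Per the labels, cells were sorted by CD4, CD8, CD69 and TCRb on the surface, cultured cells were purified again on magnetic beads, and libraries were made with the SMARTer Ultra Low Input and Nextera XT kits. The deposited values are counts of reads per gene, 1 file for each of 38 libraries. Per the submitters' processing notes, reads were aligned with STAR and counted with HTSeq on the mm10 build. The versions, the annotation and the strand setting are not given in the sources used here. Without strand information, reads of overlapping genes on opposite strands cannot be assigned with certainty. Each file held 24421 gene rows and 5 summary rows, which stayed out of library sizes and tests. Between 25.9% and 36.9% of a library's reads were counted in genes, 47.8% to 62.3% fell outside annotated features, 9.09% to 19.7% did not align uniquely and 0.161% to 0.315% were ambiguous.

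Group and replicate number were taken from the sample titles. The labels do not say whether replicates were separate mice, so p-values measure the spread between these samples. Gene counts summed to between 7783703 and 14171598 per library. A gene with no count in a library could have been present at up to 3 counts, or 0.212 to 0.385 CPM, and such limits cover counting error only, since reads without molecular identifiers are not independent molecules. Symbols were used as the files give them, and positions are from the GRCm38 annotation, which is the same assembly as mm10.

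The tests, the gene lists, the naming rule and most alternatives were fixed before the data were examined. The test was edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with robust dispersions, TMM scaling and edgeR's filter on low counts with a minimum of 10. P-values were adjusted by Benjamini and Hochberg's method over all genes tested, at a threshold of 0.05. All 30 libraries taken directly from the thymus entered 1 fit with a coefficient for each group, which gave 20 residual degrees of freedom and 11841 genes. The 8 libraries of the culture experiment entered another, with 3 residual degrees of freedom and 11544 genes. In that fit a lone library was assumed to vary like the other groups. From the first came cKO against WT in each subset, their mean, an F test and a contrast for differences between subsets, and 5 comparisons of WT subsets. Genes highest in WT ISP cells had to be at least 2-fold higher than in DN and in DP cells, at the threshold in both tests. Values after ± are standard errors. CPM is edgeR's count of a gene scaled to library size with TMM factors, and log2 CPM for principal components used a prior count of 2.

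Named genes followed a rule. Named were Brd2, Brd3, Brd4 and the sort markers. In each comparison they were joined by the 12 higher and 12 lower genes of largest log2 fold change that passed the threshold, had a mean log2 CPM of at least 3 and did not overlap between the 2 groups' libraries. For 3 libraries against 3, chance gives such separation to 10% of genes. The overlap condition was dropped for differences between subsets, and unnamed symbols were left out. From each list the 4 members of smallest p could be named. Where 1 WT library was set against 1, genes were the 12 largest ratios each way with log2 CPM of at least 5, with a pseudocount of 1. Among genes the rule allowed, preference went, after the values were seen, to those whose call no left-out library ended. Genes named for being called in all 5 subsets were picked by those calls, and Ifit1 in ISP cells was named after its values were seen.

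There were 34 gene lists, with 11 listed symbols absent from the files, and lists with at least 3 tested members were used. Members past the threshold were counted over all genes and, separately, adjusted over the list alone. Each list was compared with all other genes by camera with a preset correlation of 0.01, adjusted over the lists of a comparison. Where a call was lost with the correlation estimated from the data, that adjusted p is printed too. Of the camera calls in the culture experiment, none held with an estimated correlation. The test fry was run as another alternative.

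On simulated counts drawn from the real means and library sizes, with 200 genes changed, edgeR called 78.8% of genes changed 4-fold, 37.3% of those changed 2-fold and 11.9% of those changed 1.5-fold in the ISP comparison, among 11841 genes with 7 false calls. For the mean over 5 subsets it called 100% of 4-fold, 83.6% of 2-fold and 55.2% of 1.5-fold changes, with 4 false calls. The simulations gave each gene 1 spread in all groups. Real ISP cKO replicates correlated less (0.966 to 0.995) than ISP WT replicates (0.996 to 0.997), so the rates may not hold there.

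Alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, a fit of the compared groups alone, all 38 libraries in 1 fit for the culture comparisons, the replicate number as a block, and leaving out each library in turn. In DN cells the WT and cKO libraries with the same number deviated together from their group means (correlations of 0.20, 0.24 and 0.55), so the numbers were taken to pair them, as a hint from the data and not from the labels. Replicate 3 had the highest Lars2 and Rn45s share of both groups (7.55% in WT, 4.92% in cKO), so shared library quality could give these correlations too. Chosen after seeing the data were 3 more, namely the number within a genotype over the subsets as a block, leaving out the 3 libraries in which Lars2 and Rn45s took over 7% of the counts, and the log2 of that share as a covariate. RLE factors moved the median log2 fold change of all genes by at most 0.03 and the share of calls that were higher by at most 4.97 percentage points. A GC or length correction was not run as a setting of its own. Cultured WT cells that stayed ISP were not analysed here.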

Results

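The data were gene counts from 38 RNA libraries of sorted mouse thymocytes, labelled as carrying a deletion of Brd4 in T cells or not. BRD4 is a BET protein, which binds acetylated histones and recruits P-TEFb, the kinase that releases paused RNA polymerase II. In the conditional knockout (cKO), 1 Brd4 allele was null and the other was floxed, for removal by Lck-cre. The wild-type (WT) controls had no cre and carried 1 floxed and 1 normal allele, except DN WT replicate 3, which was labelled with 2 normal alleles. Thymocytes pass from double-negative (DN) cells through immature single-positive (ISP) cells to double-positive (DP) cells, and then to mature CD4 or CD8 single-positive cells. Each of these 5 subsets had 3 WT and 3 cKO libraries, 30 in all. The other 8 libraries came from an experiment in which ISP cells were cultured for 16 h: 1 WT and 2 cKO input libraries taken before culture, 2 libraries of cKO cells still ISP afterwards, and 1 WT and 2 cKO libraries of cells that had become DP. Total counts in genes ranged from 7783703 to 14171598 per library.

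Subsets taken directly from the thymus lay apart on the leading principal components. WT and cKO libraries overlapped on the first component in every subset. On the second they lay apart in DN, ISP and CD8 cells and overlapped in DP and CD4 cells. In the 30 libraries taken directly from the thymus, the first principal component held 47.1% of the variance and the second 19.8%. Correlations between replicates of log2 CPM (counts scaled to library size) ranged from 0.966 to 0.998. The mitochondrial leucyl-tRNA synthetase gene Lars2 and the ribosomal RNA precursor Rn45s took from 2.48% to 11.1% of the counts of these libraries, and from 0.456% to 1.16% in the culture experiment. Their share was over 7% in 3 libraries: ISP cKO replicate 3 (11.1%), CD8 cKO replicate 1 (8.57%) and DN WT replicate 3 (7.55%). Brd4 counts moved with it.

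**Figure D1:**
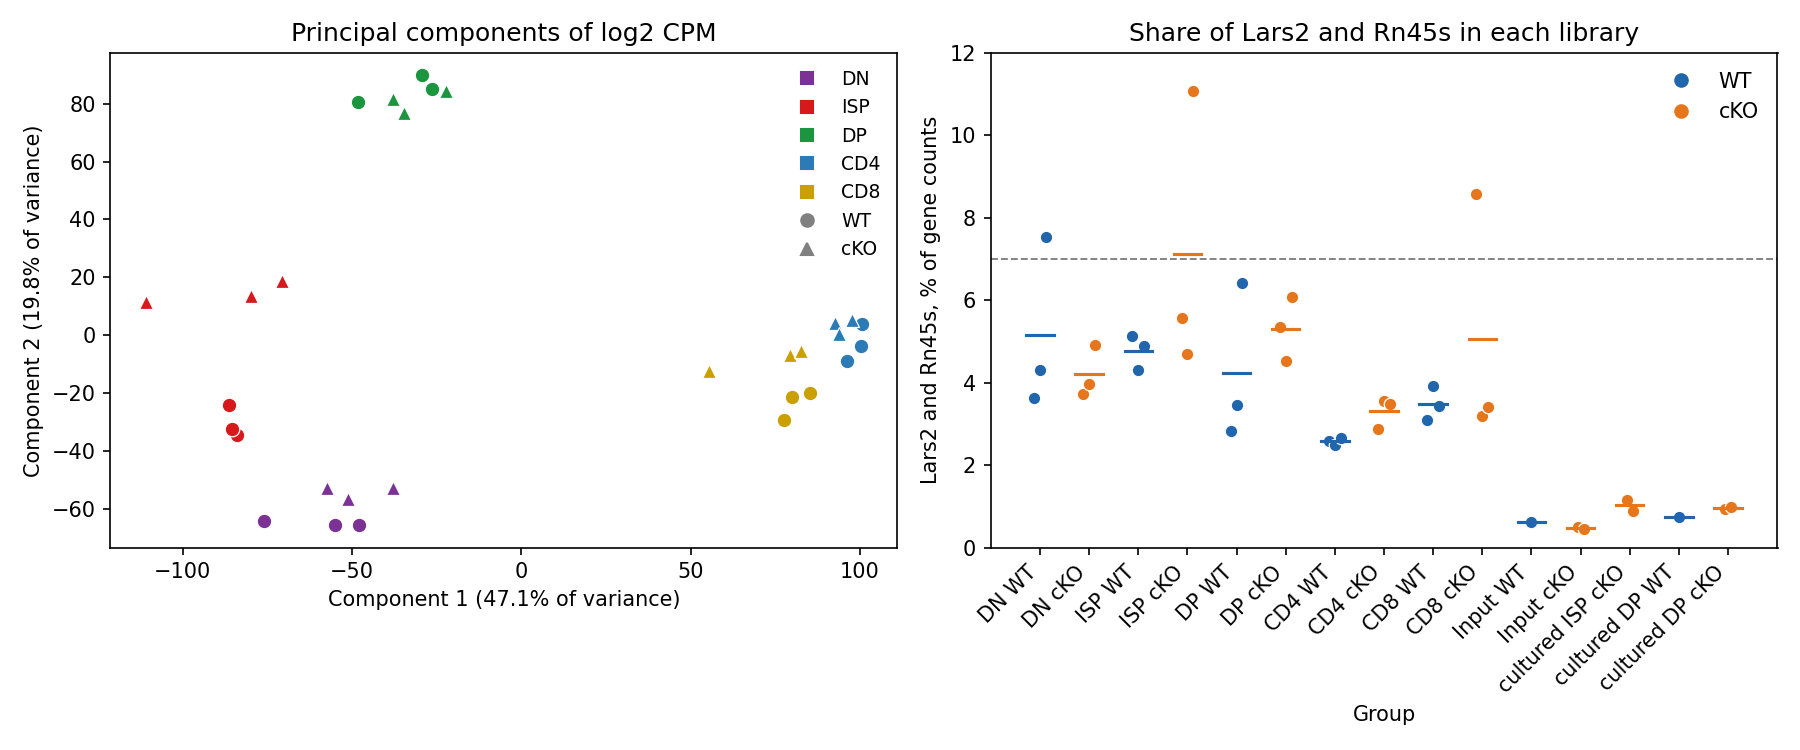
Left, the 30 libraries taken directly from the thymus on the first 2 principal components of log2 CPM (axes give the percent of variance), coloured by subset, with circles for WT and triangles for cKO. Right, the percent of gene counts from Lars2 and Rn45s in each of the 38 libraries, where 3 lie above 7%, marked by a dashed line, and bars give group means.

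Brd4 itself (chromosome 17, 32196274 to 32284722, GRCm38) passed the test in DP cells and in no other subset. The counts cover the whole gene, so they cannot show whether the floxed exon was removed and check no label. In DP cells Brd4 fell by 2.06 ± 0.55 on the log2 scale (SE, 3 libraries per group, edgeR adjusted p = 0.0257), with 123, 215 and 66.5 CPM in the WT libraries and 28.99, 35.2 and 32.96 CPM in the cKO libraries. The call ended without any 1 of 5 of the 6 DP libraries. Its log2 fold change was then −2.12 without WT replicate 1, −1.55 without WT replicate 2, and −1.94, −2.10 and −2.01 without cKO replicates 1, 2 and 3. The log2 fold change was −0.00 ± 0.53 in DN, −0.63 ± 0.53 in ISP, −0.12 ± 0.52 in CD4 and −0.55 ± 0.53 in CD8 cells (adjusted p = 1, 0.424, 0.979 and 0.696). The 5 effects on Brd4 did not pass the test of a difference between subsets (adjusted p = 0.284). Brd4 was lowest in libraries with a high Lars2 and Rn45s share: 9.23 CPM in ISP cKO replicate 3, against 51.8 and 58.3 CPM in the other ISP cKO libraries, and 17.1 CPM in DN WT replicate 3, against 76.7 and 83.4 CPM. In the input of the culture experiment Brd4 was at 132 CPM in WT and 93.7 and 91.1 CPM in cKO cells (log2 fold change −0.52 ± 0.22, adjusted p = 0.118). The related Brd2 and Brd3 passed the edgeR threshold in 0 of the 5 subsets, with 0 at an unadjusted p under 0.05 and 0 called by DESeq2.

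**Figure D2:**
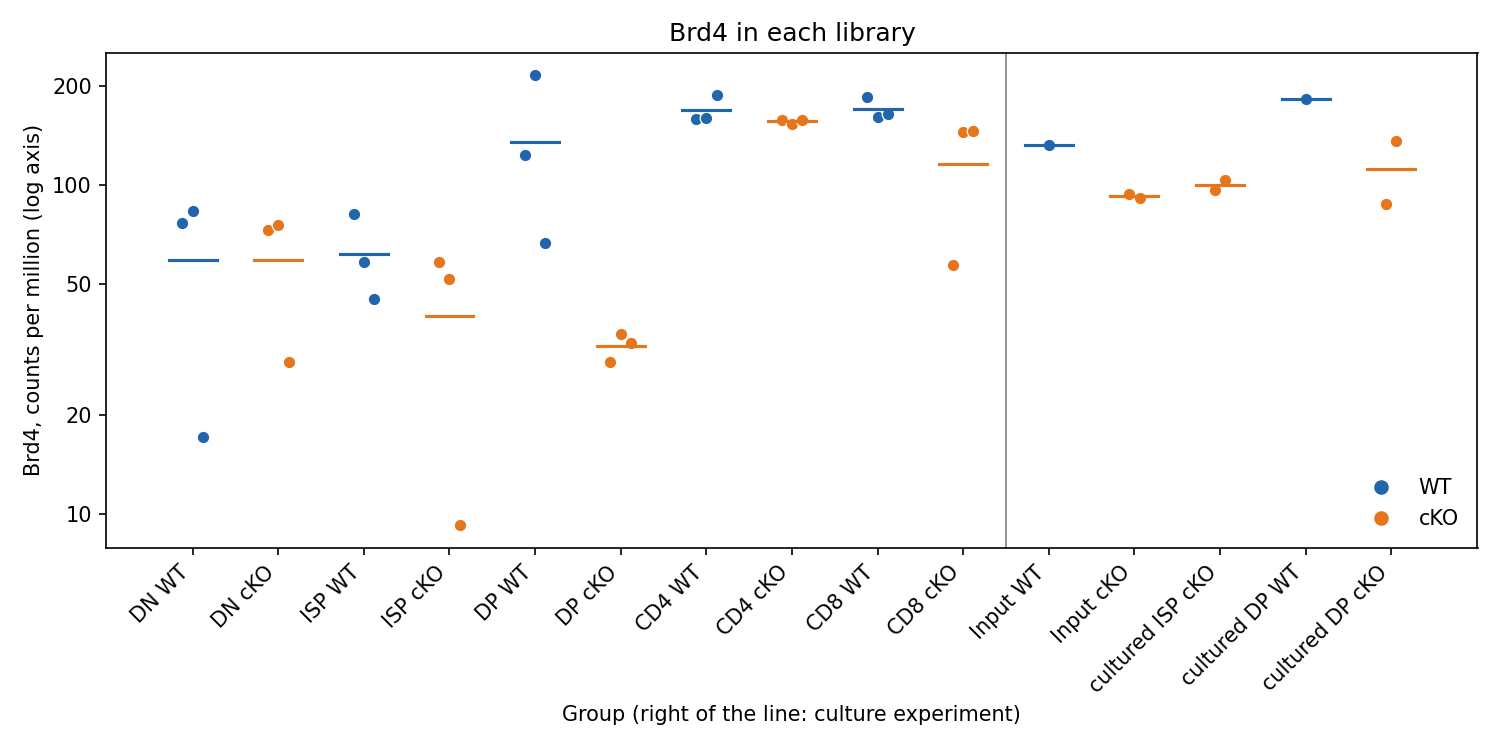
Brd4 in each of the 38 libraries. Each point is 1 library (TMM-scaled CPM, log axis), WT in blue and cKO in orange, and bars mark group means. The 3 DP cKO libraries lie between 29.0 and 35.2 CPM, below the 3 DP WT libraries, while the CD4 libraries of both genotypes lie between 153 and 187 CPM.

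The first question was how cells labelled cKO differed from WT in each subset. The number of genes past an adjusted p of 0.05 differed widely. In ISP cells 3145 of 11841 genes differed, against 120 in DN, 685 in DP, 695 in CD4 and 599 in CD8 cells. This order depended on how the spread was estimated, because a fit to the compared groups alone called 647 genes in ISP and 1775 in CD4 cells.

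**Figure D3:**
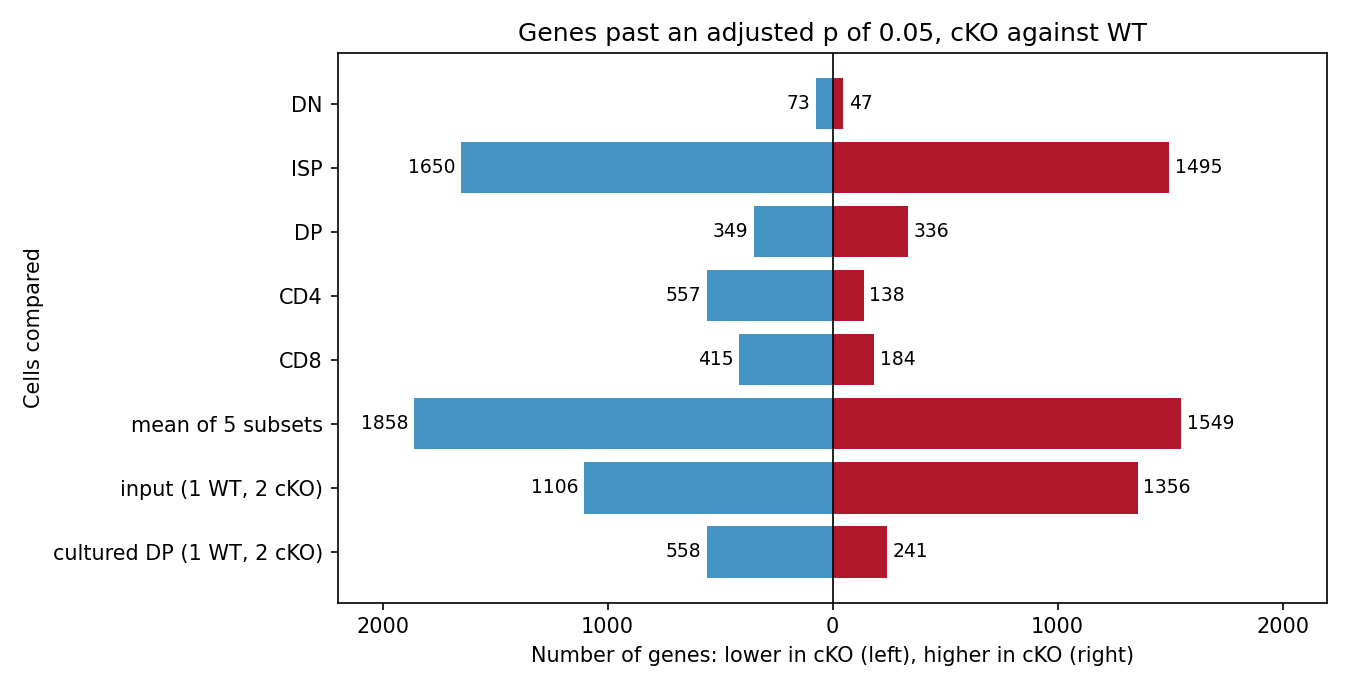
Genes past an edgeR adjusted p of 0.05, cKO against WT, in each subset, for the mean of the subsets and in the culture experiment. Bars to the right count genes higher in the cKO and bars to the left genes lower in the cKO, from 0. ISP cells had 1495 higher and 1650 lower genes.

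DN cells had the fewest genes called of the 5 subsets. The histone gene Hist1h2bc, which makes a histone H2B, rose in the cKO (log2 fold change 1.94 ± 0.28, 3 libraries per group), as did the adhesion receptor gene Adgre5 (1.77 ± 0.24) and the apoptosis-related Phlda1 (1.57 ± 0.27). The chemokine receptor gene Ccr9 (−1.37 ± 0.22) and the neuronal factor gene Mturn (−1.29 ± 0.21) fell. Of 120 genes called, 47 were higher and 73 lower. Among 24 interferon response genes, 8 were higher and none lower (20 and 0 adjusted over the list alone, 16 not past the threshold; adjusted p = 1.4e-23, or 0.109 with an estimated correlation). In the dendritic cell marker list (12 tested), 2 were lower and none higher (0 and 6 adjusted over the list alone, 10 not past the threshold; adjusted p = 0.000129, or 0.109 with an estimated correlation). With the WT and cKO libraries of a number as pairs, 49 genes were called, 14 higher and 35 lower. In that fit edgeR called 0 of the 24 interferon response genes, with 20 at an unadjusted p under 0.05 and a list p, adjusted, of 2.66e-21, or 0.248 with an estimated correlation. Of the 12 dendritic cell markers it called 1 lower and none higher (camera adjusted p = 0.000136, or 0.248 with an estimated correlation). Fitted to DN libraries alone, edgeR called 0 genes, with 979 of 11106 genes at an unadjusted p under 0.05, and DESeq2 called 355. The count was 36 without WT replicate 1, 20 without WT replicate 3, and 19, 17 and 45 without cKO replicates 1, 2 and 3. With the Lars2 and Rn45s share as a covariate it was 422.

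Growth genes fell in cKO ISP cells. Myc, the transcription factor that drives ribosome production and growth (chromosome 15, 61985391 to 61990374), fell by 2.36 ± 0.34 on the log2 scale (SE, 3 libraries per group), from 258, 217 and 186 CPM in the WT libraries to 50.05, 61.8 and 16.3 CPM in the cKO. Polr1b, a subunit of RNA polymerase I, fell (−2.20 ± 0.15), with the polyamine enzyme gene Srm (−1.86 ± 0.19) and the amino acid aminotransferase gene Bcat1 (−2.90 ± 0.34). The cytokine receptor gene Il7r (−2.38 ± 0.34), the pre-T cell receptor gene Ptcra (−1.63 ± 0.33) and the homing receptor gene Sell (−2.35 ± 0.32) also fell. The histone genes Hist1h2bc (chromosome 13, 23684199 to 23692908) and Hist2h2be rose, by 3.76 ± 0.30 and 3.11 ± 0.29. Higher too were the quiescence factor gene Klf2 (2.67 ± 0.29), the death receptor gene Fas (1.93 ± 0.17), the antiproliferative Btg1 (2.48 ± 0.18), the recombinase gene Rag1 (1.52 ± 0.33) and Cd8a (1.20 ± 0.21). The nuclear RNA Malat1, on the list of RNA quality genes, rose by 1.66 ± 0.40, with 979.5, 945 and 1050 CPM in WT and 2199, 2851 and 4345 CPM in cKO libraries. It also rose in WT from ISP to DP cells (2.38 ± 0.41).

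The gene lists fixed beforehand gave the same groups. Of 30 MYC and ribosome biogenesis genes, 1 was higher and 24 were lower (1 and 26 adjusted over the list alone, 5 not past the threshold; adjusted p = 1.05e-18). Glycolysis genes followed, with Slc2a3, a glucose transporter gene, at −1.63 ± 0.14 and Aldoa at −1.20 ± 0.14. Of 19 tested, 16 were lower and none higher (0 and 16 adjusted over the list alone, 3 not past the threshold; adjusted p = 4.97e-10). For 21 nucleotide and one-carbon synthesis genes, 14 were lower and none higher (0 and 15 adjusted over the list alone, 7 not past the threshold; adjusted p = 8.98e-13), with Atic at −1.38 ± 0.12 and Shmt2 at −1.64 ± 0.17. Of 21 genes of ATF4 and ER stress, 1 was higher and 7 were lower (1 and 9 adjusted over the list alone, 13 not past the threshold; adjusted p = 0.00429), with the amino acid transporter gene Slc7a5 at −1.47 ± 0.17. Among 30 DNA replication genes, 13 were lower and none higher (0 and 16 adjusted over the list alone, 17 not past the threshold; adjusted p = 2.98e-05, or 0.373 with an estimated correlation). No mitosis gene of 30 passed the edgeR threshold (camera adjusted p = 0.528), with 2 at an unadjusted p under 0.05 and 2 called by DESeq2.

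Many members of the interferon and histone lists rose in ISP cells. Of 24 interferon response genes, 18 were higher and 1 was lower (19 and 1 adjusted over the list alone, 5 not past the threshold; adjusted p = 8.51e-09, or 0.224 with an estimated correlation), with the nucleic acid sensor gene Zbp1 at 2.60 ± 0.27 and Stat1 at 1.53 ± 0.27. Of 26 replication-dependent histone genes, 12 were higher and none lower (16 and 0 adjusted over the list alone, 14 not past the threshold; adjusted p = 4.97e-10, or 0.224 with an estimated correlation). Among 19 p53 targets, 7 were higher and none lower (7 and 1 adjusted over the list alone, 12 not past the threshold; adjusted p = 0.00818, or 0.224 with an estimated correlation). Dendritic cell markers were lower. Cd74, the invariant chain of class II antigen presentation (chromosome 18, 60803848 to 60812652), fell by 4.49 ± 0.63, from 76.03, 98.3 and 102 CPM in WT to 5.70, 2.998 and 3.61 CPM in cKO libraries. The class II gene H2-Aa changed by −4.35 ± 0.66, and of 12 dendritic cell markers 1 was higher and 7 were lower (1 and 9 adjusted over the list alone, 4 not past the threshold; adjusted p = 0.00038, or 0.0865 with an estimated correlation). The ISP count ranged from 2201 without WT replicate 2 to 3703 without cKO replicate 2.

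**Figure D4:**
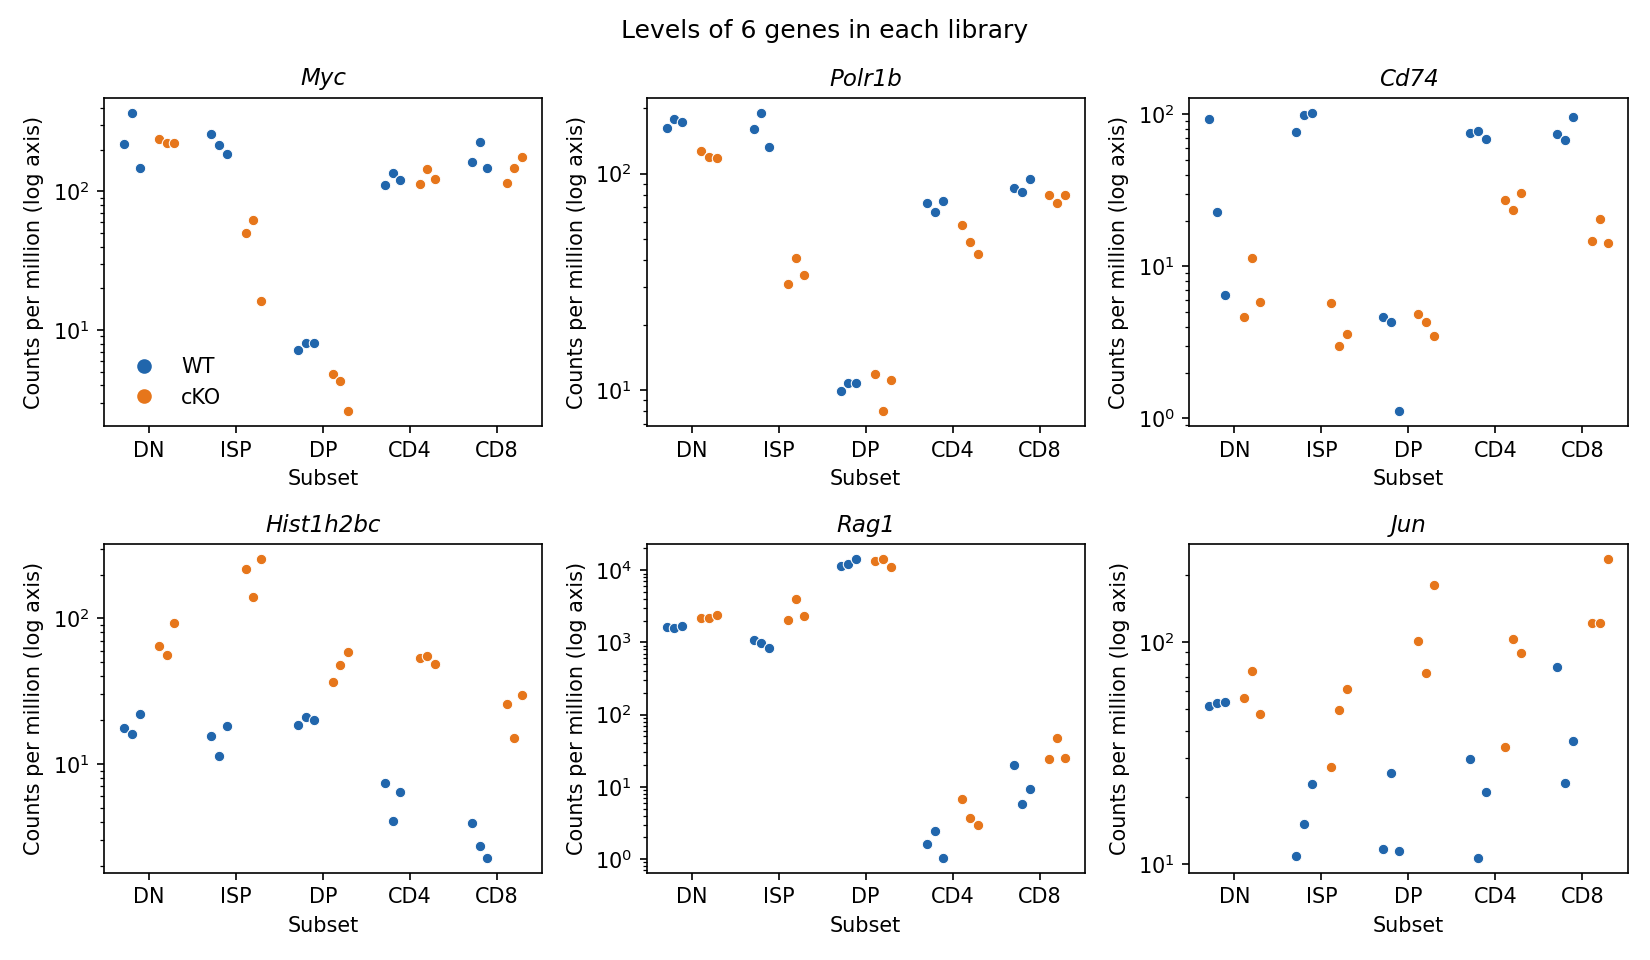
Levels of 6 genes in each library of the 5 subsets. Each point is 1 library (TMM-scaled CPM, log axis), WT in blue and cKO in orange. Myc, Polr1b and Cd74 are lower and Hist1h2bc and Rag1 higher in cKO than in WT ISP libraries, without overlap between the genotypes.

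In DP cells of the cKO, immediate-early response genes rose, and so did 3 genes of class I antigen presentation, which had no list of their own. The class I genes H2-K1 (2.10 ± 0.28) and H2-D1 (1.44 ± 0.24) and their partner B2m (1.47 ± 0.24) rose (3 libraries per group). So did the AP-1 factor gene Jun (2.86 ± 0.51), the receptor-induced Nr4a1 (1.28 ± 0.24), the survival gene Bcl2 (1.46 ± 0.30) and the adrenergic receptor gene Adrb2 (3.27 ± 0.44). Lower genes included the cystine transporter gene Slc7a11 (−2.93 ± 0.52), the scaffold gene Akap12 (−3.61 ± 0.69) and Ly6d (−2.57 ± 0.48). In all, 685 genes were called, 336 higher and 349 lower. Of 20 immediate-early response genes, 11 were higher and none lower (16 and 0 adjusted over the list alone, 9 not past the threshold; adjusted p = 8.07e-12). Of 28 genes of positive selection and maturation, 12 were higher and 1 was lower (12 and 2 adjusted over the list alone, 15 not past the threshold; adjusted p = 7.06e-09). Of 24 interferon response genes, 12 were higher and 1 was lower (18 and 1 adjusted over the list alone, 11 not past the threshold; adjusted p = 1.53e-15, or 0.2 with an estimated correlation), with Isg15 at 2.36 ± 0.41 and Irf7 at 2.03 ± 0.34. Of 30 DNA replication genes, 6 were lower and none higher (0 and 15 adjusted over the list alone, 24 not past the threshold; adjusted p = 6.58e-10, or 0.443 with an estimated correlation).

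Long transcripts were over-represented among the genes lower in cKO DP cells. Their median length was 3689 bases, against 3354 for all tested genes. Across genes, which are not independent replicates, the Spearman correlation of the DP log2 fold change with transcript length was −0.23. It was 0.02 with the Lars2 and Rn45s share as a covariate. Other subsets had 0.25 (DN), −0.16 (ISP), −0.04 (CD4) and −0.03 (CD8), so a length trend was not particular to DP cells. The 3 DP cKO libraries had shares of 5.35%, 4.52% and 6.07%, against 2.83% and 3.45% in WT replicates 1 and 2 and 6.41% in WT replicate 3. Malat1 was at 2772, 5201 and 7522 CPM in the DP WT and 10044, 8047 and 15038 CPM in the DP cKO libraries. Of the 7 genes tested on its RNA quality list, none passed the edgeR threshold and DESeq2 called 2. The DP count was 374 without WT replicate 1, 333 without WT replicate 2, 249 without cKO replicate 2 and 317 without cKO replicate 3. It was 1162 by DESeq2, 1205 with the share as a covariate and 2876 without the 3 libraries over 7%, none of which is a DP library.

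Mature CD4 cells had more lower than higher genes, 557 against 138. Ccr4 and Ccr8, chemokine receptor genes of activated and selected T cells, fell (−3.53 ± 0.49 and −2.87 ± 0.34, 3 libraries per group), as did the late thymocyte gene Dapl1 (−3.50 ± 0.54), the choline enzyme gene Chdh (−4.25 ± 0.59) and the transglutaminase gene F13a1 (−3.90 ± 0.47). Cd8a (−1.98 ± 0.30) and Cd8b1 (−1.75 ± 0.22) were lower. The sort marker Cd8a was at low levels here, with 2.68, 4.93 and 3.23 CPM in WT and 1.38, 0.685 and 0.732 CPM in cKO libraries. In WT CD8 libraries it was at 1915, 2098 and 1808 CPM. Foxp3, the regulatory T cell factor gene, fell (−0.95 ± 0.20) with Tnfrsf4 (−1.55 ± 0.33). Hist1h2bc (3.14 ± 0.30), the zinc finger gene Cxxc5 (2.66 ± 0.17) and Junb (1.83 ± 0.39) rose. Of 20 DP-stage genes, 7 were lower and none higher (1 and 7 adjusted over the list alone, 13 not past the threshold; adjusted p = 6.7e-05, or 0.113 with an estimated correlation). For glycolysis (19 genes), 5 were lower and none higher (0 and 8 adjusted over the list alone, 14 not past the threshold; adjusted p = 0.000268, or 0.148 with an estimated correlation). Immediate-early response genes (20 tested) were called in 1 direction, as 4 were higher and none lower (5 and 0 adjusted over the list alone, 16 not past the threshold; adjusted p = 6.7e-05, or 0.0909 with an estimated correlation). The CD4 count was 384 and 450 without WT replicates 2 and 3, and 452, 398 and 351 without cKO replicates 1, 2 and 3. A fit of the CD4 libraries alone called 1775. The count was 1345 without the 3 libraries of high Lars2 and Rn45s share, none of them a CD4 library, and 2099 with the share as a covariate.

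CD8 cells shared many of these changes. Ccr8 (−4.48 ± 0.40), Dapl1 (−4.12 ± 0.47), the stem cell factor receptor gene Kit (−2.64 ± 0.37) and the T cell receptor brake gene Cd5 (−1.16 ± 0.22) fell (3 libraries per group). Hist1h2bc (2.98 ± 0.31), the granzyme gene Gzma (1.73 ± 0.35), the p53 target Phlda3 (1.86 ± 0.26) and the interferon-induced Ifi44 (3.03 ± 0.64) rose. Of 599 genes called, 184 were higher and 415 lower. Of 19 glycolysis genes, 4 were lower and none higher (0 and 5 adjusted over the list alone, 15 not past the threshold; adjusted p = 0.000157, or 0.297 with an estimated correlation). Of 20 immediate-early response genes, 6 were higher and none lower (9 and 1 adjusted over the list alone, 14 not past the threshold; adjusted p = 0.0031, or 0.297 with an estimated correlation). Of 30 DNA replication genes, 1 was lower and none higher (0 and 1 adjusted over the list alone, 29 not past the threshold; adjusted p = 8.83e-06, or 0.498 with an estimated correlation). The CD8 count was 374, 390 and 288 without WT replicates 1, 2 and 3, and 396 and 330 without cKO replicates 1 and 3. In a fit of the CD8 libraries alone it was 266, and DESeq2 called 919. With the Lars2 and Rn45s share as a covariate 1604 were called.

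**Figure D5:**
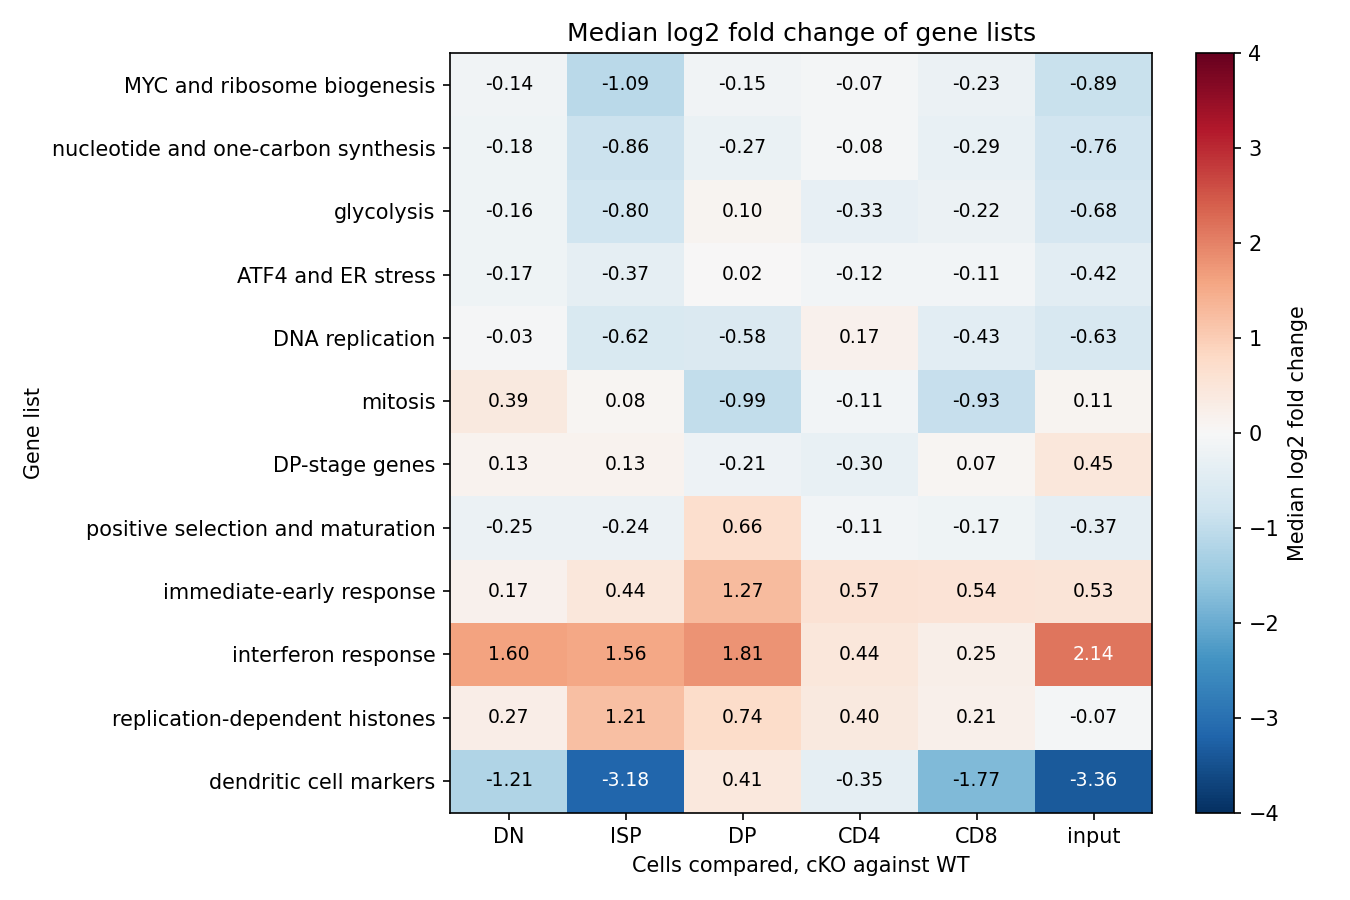
Median log2 fold change, cKO against WT, of the tested members of 12 gene lists in each subset and in the input of the culture experiment. Colour runs from blue (lower in the cKO) to red (higher), and each cell gives its median. The MYC and ribosome biogenesis list has its lowest median in ISP cells and the interferon response list is above 0 in all 6 columns.

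Some genes changed in every subset. Hist1h2bc and the unnamed AW011738 were higher in the cKO in all 5, and Cd96, Dok2, Fam174b, Hvcn1, Pglyrp2, Tbxa2r and Tctn1 were lower in all 5. These 9 were picked by their calls. Most genes called, 3071, were called in 1 subset, and 2454 of the 3145 called in ISP cells were called there alone. Of 590 genes called in 2 subsets, 538 went the same way. CD4 and CD8 cells shared 247 genes lower in both (19.5 if the calls were independent) and 56 higher in both (2.14 if independent).

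Averaged over the 5 subsets, 3407 genes differed between the genotypes, 1549 higher and 1858 lower. Hist1h2bc rose by 2.62 ± 0.13, the antiviral genes Ifi44 (3.02 ± 0.33) and Oas1a (2.45 ± 0.26) rose, and so did Adrb2 (2.10 ± 0.19) (15 WT and 15 cKO libraries). The test took these libraries as independent. Those of 1 genotype and number correlated between some subsets (0.258, 0.421 and 0.579 for DN and ISP cKO), so standard errors may be too small and the count too high. The block over the subsets was not run for this mean. The signalling adaptor gene Dok2 (−1.61 ± 0.13), Traf1 (−1.95 ± 0.17), Cd74 (−2.07 ± 0.26) and Cd5 (−0.83 ± 0.10) fell. HEXIM proteins hold P-TEFb inactive, and the average of Hexim1 (−0.37 ± 0.09) and Hexim2 (−1.24 ± 0.12) fell while the P-TEFb cyclin genes Ccnt1 (0.26 ± 0.06) and Ccnt2 (0.39 ± 0.08) rose. Of 19 glycolysis genes, 12 were lower and none higher (0 and 13 adjusted over the list alone, 7 not past the threshold; adjusted p = 1.56e-07). Immediate-early response genes rose on average, as of 20 tested 12 were higher and none lower (13 and 0 adjusted over the list alone, 8 not past the threshold; adjusted p = 1.91e-07). Interferon response genes did so as well: of 24 tested, 19 were higher and none lower (19 and 0 adjusted over the list alone, 5 not past the threshold; adjusted p = 1.27e-17, or 0.148 with an estimated correlation). Brd4 was lower on average (−0.67 ± 0.24, adjusted p = 0.0356). That call ended with the Lars2 and Rn45s share as a covariate (−0.32 ± 0.16, adjusted p = 0.112, range over its alternatives 0.00498 to 0.112). It also ended without any 1 of 15 of the 30 libraries: DN WT replicate 1 (−0.62) or 2 (−0.60), DN cKO 3 (−0.60), ISP WT 1 (−0.60) or 2 (−0.66), DP WT 2 (−0.57), DP cKO 1 (−0.63), 2 (−0.67) or 3 (−0.65), CD4 WT 1 (−0.66) or 3 (−0.65), CD4 cKO 2 (−0.67), CD8 WT 1 (−0.66) or 3 (−0.66) and CD8 cKO 1 (−0.59).

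Whether the cKO effect differed between subsets was tested directly. An F test of the 5 effects found 929 genes, and the ISP effect less the mean of the other 4 found 1355, 607 higher and 748 lower. The ISP effect lay below the mean of the others for Polr1b (difference −1.89 ± 0.17) and above it for Klf2 (2.20 ± 0.31), Fas (1.84 ± 0.19), Btg1 (2.04 ± 0.19) and Cd8a (1.71 ± 0.24), which rose in ISP cells and fell in CD4 cells. In CD4 libraries Cd8a was at most 4.93 CPM, so its difference rests in part on a low level. For Il7r (−3.47 ± 0.40) part of the difference came from other subsets, since it fell in ISP and rose in DP cells. In the WT DP libraries Il7r lay near the limit of 3 counts, so the size of this difference is uncertain. Of 30 MYC and ribosome biogenesis genes, 17 were lower and none higher (0 and 20 adjusted over the list alone, 13 not past the threshold; adjusted p = 8.68e-22). Of 19 glycolysis genes, 9 were lower and none higher (0 and 12 adjusted over the list alone, 10 not past the threshold; adjusted p = 7.9e-08). Against single subsets, in tests that were not part of the design fixed beforehand, the ISP effect differed from that in DN cells for 559 genes, in DP for 945, in CD4 for 866 and in CD8 for 603. With the WT and cKO libraries of a number as pairs, as was assumed for DN cells, the F test called 607 genes. Without ISP WT replicate 2 the F test called 612 genes and the ISP difference 771, and without ISP cKO replicate 2 the ISP difference called 2127. Without the 3 libraries of high Lars2 and Rn45s share the F test called 2608 genes and the ISP difference 2064, with the share as a covariate 2661 and 2700, and DESeq2 called 1912 for the F test.

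The WT libraries show where ISP cells stand in normal development. From DN to ISP, 1184 genes rose and 1800 fell. Cd8a rose (6.74 ± 0.27, 3 libraries per group), with Cd8b1 (3.90 ± 0.24) and the mitosis genes Nusap1 (2.54 ± 0.43) and Aurka (2.09 ± 0.31). The cytokine receptor genes Il2ra (−6.14 ± 0.53) and Il7r (−3.52 ± 0.29) and the Notch target Hes1 (−3.58 ± 0.31) fell. Of 30 mitosis genes, 27 were higher and none lower (28 and 0 adjusted over the list alone, 3 not past the threshold; adjusted p = 1.72e-15, or 0.152 with an estimated correlation). Of 17 DN-stage genes, 13 were lower and none higher (0 and 14 adjusted over the list alone, 4 not past the threshold; adjusted p = 1.72e-12). In a fit of DN and ISP WT libraries alone 1475 genes were called, with 4740 without the 3 libraries of high Lars2 and Rn45s share and 4858 with the share as a covariate.

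From ISP to DP cells, WT growth genes fell. Myc changed by −4.82 ± 0.38, Polr1b by −3.93 ± 0.17 and Srm by −4.79 ± 0.22 on the log2 scale (3 libraries per group). Cd4 (5.79 ± 0.49), Rag1 (3.70 ± 0.36), the sodium channel subunit gene Scn4b (5.91 ± 0.38) and the receptor chain gene Cd247 (1.84 ± 0.13) rose. In total 3406 genes were higher and 3487 lower. Of 30 MYC and ribosome biogenesis genes, 1 was higher and 25 were lower (1 and 25 adjusted over the list alone, 4 not past the threshold; adjusted p = 5.87e-17). Of 30 DNA replication genes, 30 were lower and none higher (0 and 30 adjusted over the list alone, 0 not past the threshold; adjusted p = 2.64e-20). T cell receptor signalling genes rose, as of 24 tested 22 were higher and none lower (23 and 0 adjusted over the list alone, 2 not past the threshold; adjusted p = 6.93e-09). At least 2-fold higher in ISP cells than in both DN and DP cells were 254 genes, where 79.7 would be if the 2 comparisons were independent, and 0 were found in any of 5 simulations without differences. Both comparisons use the same 3 ISP libraries. The simulations gave each gene 1 mean in all groups, so a count near 0 was fixed in advance. Of the 254 genes, 26 were mitosis genes and 7 were in the 2 lists of dendritic cell genes (H2-Aa, H2-Ab1, H2-Eb1, Irf5, Naaa, Siglech and Xcr1, named by this count), so the count may not describe thymocyte genes alone.

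From DP to mature cells, 2805 genes rose and 2655 fell in CD4 cells, and 3029 rose and 2637 fell in CD8 cells. The mean of Il7r was 505 CPM in CD4 cells, against 0, 0 and 0.171 CPM in the DP libraries, and that of the egress receptor gene S1pr1 was 621 CPM, against 0, 0 and 0.513 CPM. Klf2 rose in CD4 (6.76 ± 0.32) and CD8 cells (6.73 ± 0.32), and H2-K1 rose in both (6.90 ± 0.34 and 7.24 ± 0.35). Rag1 had a mean of 12576 CPM in DP, 1.71 in CD4 and 11.7 CPM in CD8 cells. Of 28 genes of positive selection and maturation, in CD4 cells 25 were higher and none lower (26 and 0 adjusted over the list alone, 3 not past the threshold; adjusted p = 6.17e-24). In CD8 cells the counts were close, as 24 were higher and 1 was lower (24 and 1 adjusted over the list alone, 3 not past the threshold; adjusted p = 4.47e-17). Of 20 DP-stage genes, in CD4 cells 1 was higher and 16 were lower (1 and 18 adjusted over the list alone, 3 not past the threshold; adjusted p = 6.5e-33), and in CD8 cells 1 was higher and 19 were lower (1 and 19 adjusted over the list alone, 0 not past the threshold; adjusted p = 8.88e-26).

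CD4 and CD8 cells differed in 1731 genes, 770 higher in CD4 and 961 higher in CD8 cells. Cd4 (8.97 ± 0.58), the lineage factor gene Zbtb7b (9.58 ± 0.68) and the helper cell gene Cd40lg (5.92 ± 0.47) were higher in CD4 cells, and Cd8a (−9.05 ± 0.29), Nkg7 (−7.64 ± 0.58) and the integrin gene Itgae (−7.29 ± 0.62) higher in CD8 cells (3 libraries per group). Of 30 DNA replication genes, 29 were lower and none higher (0 and 30 adjusted over the list alone, 1 not past the threshold; adjusted p = 2.93e-22). A fit of these libraries alone called 3688 genes, and 3031 were called without the libraries of high Lars2 and Rn45s share and 3232 with the share as a covariate.

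In the culture experiment ISP cells of the 2 genotypes became DP cells. Its input repeated the ISP comparison in separate libraries, 1 WT and 2 cKO, where the lone WT library was assumed to vary like the other groups. In it 1356 genes were higher and 1106 lower in the cKO. Hist1h2bc (2.95 ± 0.19), Rag1 (2.37 ± 0.14), the signalling inhibitor gene Socs3 (2.68 ± 0.29) and Adrb2 (2.84 ± 0.26) rose. Srm (−1.71 ± 0.17), the glycolysis gene Tpi1 (−1.75 ± 0.16), Cd74 (−3.79 ± 0.36) and Sell (−2.02 ± 0.19) fell. Malat1 rose here too (1.94 ± 0.26), with 733 CPM in WT and 3313 and 2310 CPM in cKO cells. Of 3099 genes called in the ISP cells taken from the thymus and tested here, 2608 (84.2%) moved the same way, with a correlation of log2 fold changes of 0.721 across these genes and 0.468 across all 11247 genes tested in both. Called in both were 947, against 337 if the calls were independent, and 927 of these moved the same way. Of 30 MYC and ribosome biogenesis genes, 1 was higher and 24 were lower (1 and 28 adjusted over the list alone, 5 not past the threshold; adjusted p = 1.13e-14, or 0.179 with an estimated correlation). All 30 ribosomal protein genes tested were lower (adjusted p = 8.94e-39, or 0.18 with an estimated correlation), with a median of −1.18 against −0.14 in the ISP cells taken from the thymus. The input count was 1265 without cKO replicate 1 and 1106 without cKO replicate 2.

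During culture most DNA replication genes fell, both in cKO cells that stayed ISP and in those that became DP. In cells still ISP, 2419 genes rose and 2614 fell against the cKO input (2 libraries per group). Srm changed by −4.80 ± 0.19, the cyclin gene Ccne1 by −4.72 ± 0.22 and the helicase gene Mcm2 by −2.97 ± 0.11, while Cd4 rose by 2.03 ± 0.17, Rag1 by 1.93 ± 0.10 and Scn4b by 5.90 ± 0.27. In cells that became DP, 2791 rose and 2983 fell, with Cd4 at 4.16 ± 0.19, Rag1 at 2.52 ± 0.11, Srm at −4.40 ± 0.19 and the topoisomerase gene Top2a at −2.78 ± 0.12. Of 30 DNA replication genes, in cells still ISP 1 was higher and 29 were lower (1 and 29 adjusted over the list alone, 0 not past the threshold; adjusted p = 9.87e-25, or 0.149 with an estimated correlation). In cells that became DP, of the same list 1 was higher and 29 were lower (1 and 29 adjusted over the list alone, 0 not past the threshold; adjusted p = 1.2e-22, or 0.211 with an estimated correlation). DP-stage genes rose in both: of 20 tested, in cells still ISP 16 were higher and 1 was lower (17 and 1 adjusted over the list alone, 3 not past the threshold; adjusted p = 4.11e-08, or 0.133 with an estimated correlation), and in cells that became DP 18 were higher and 2 were lower (18 and 2 adjusted over the list alone, 0 not past the threshold; adjusted p = 4.51e-09, or 0.142 with an estimated correlation). 

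Cultured DP and cultured ISP cells of the cKO differed in 449 genes, 73 higher and 376 lower in DP cells (2 libraries per group). Cd4 rose by 2.12 ± 0.17 and the kinase gene Txk by 1.29 ± 0.19. The one-carbon enzyme genes Shmt2 (−1.15 ± 0.14) and Mthfd2 (−1.69 ± 0.21) and the mitosis genes Zwilch (−1.91 ± 0.21) and Top2a (−1.45 ± 0.12) fell. Of 30 mitosis genes, 29 were lower and none higher (0 and 30 adjusted over the list alone, 1 not past the threshold; adjusted p = 6.93e-65, or 0.241 with an estimated correlation). The count was 272 without cultured ISP replicate 1, 245 without cultured DP replicate 1 and 120 without cultured DP replicate 2.

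Cultured DP cells of the cKO, 2 libraries, were set against the 1 library of WT cells that became DP. The lone WT library was assumed to vary like the other groups. Under that assumption 241 genes were higher and 558 lower in the cKO. Hist1h1c (3.09 ± 0.24), Hist1h2bc (1.59 ± 0.17) and Socs3 (2.22 ± 0.25) rose, and Ly6d (−3.58 ± 0.16), Slc7a11 (−3.37 ± 0.20), Polr1b (−1.78 ± 0.23) and Mcm2 (−1.19 ± 0.13) fell. Of 30 mitosis genes, 26 were lower and none higher (0 and 29 adjusted over the list alone, 4 not past the threshold; adjusted p = 2e-34, or 0.649 with an estimated correlation). Of 30 DNA replication genes, 16 were lower and none higher (0 and 25 adjusted over the list alone, 14 not past the threshold; adjusted p = 5.68e-19, or 0.649 with an estimated correlation). The count was 340 without cKO replicate 1 and 266 without cKO replicate 2.

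The WT part of the culture was 1 input library against 1 library of cells that became DP, so its differences have no replicate check. Cd4 went from 38.2 to 1145 CPM (log2 ratio 4.87), Rag1 had a log2 ratio of 4.03 and the transporter gene Slc6a19 had 8.07. Srm fell by 6.29 and Cad, an enzyme gene of pyrimidine synthesis, by 6.15, while Myc fell by 1.70. Against 10000 random lists matched on expression, the median of the DNA replication list (−2.98) and that of the MYC and ribosome biogenesis list (−2.63) lay at percentile 0, and that of the DP-stage list (1.51) at percentile 100. These percentiles describe these 2 libraries.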

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

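Tests chosen only after the result was seen were those of the Lars2 and Rn45s share as the source of the ISP count and of the Brd4 difference, and of DP cells in the cKO ISP sort. The comparisons of the ISP effect with single subsets were also added later.

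The effect of the knockout differed between subsets by tests of the difference itself. The F test over the 5 effects called 929 genes, and the ISP effect less the mean of the other subsets 1355. The ISP effect differed from the DN effect in 559 genes, from the DP effect in 945, from the CD4 effect in 866 and from the CD8 effect in 603. Of 100 groupings of the 30 libraries within subsets, the real one included, 3 gave an F test with as many genes, the highest other being 1325. That share is under 0.05, but the groupings drew labels in each subset separately, as if libraries of different subsets were independent. Such groupings also remove the effect common to all subsets, and both others left the ISP libraries by genotype, so this share is no test of the difference between subsets. For the ISP difference 10 of the 100 gave as many, the highest other being 2228. All 9 others were among the 10 groupings that left the ISP libraries by genotype, while the 89 that mixed them gave at most 1. As about 1 in 10 such groupings leaves the ISP libraries by genotype, this share says nothing on chance.

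ISP cells had the most genes called, and differences between genotypes made from different libraries had a median covariance across genes of 0.429 in ISP cells (0.217 to 0.534 over 18 pairs), against 0.119 in DN, 0.223 in DP, 0.258 in CD4 and 0.196 in CD8 cells, where the DP values reached 0.506. The ISP range reaches below the DP and CD4 medians, so a larger effect and an unequal spread between groups cannot be told apart, and the fit of compared groups alone called 647 genes in ISP against 1775 in CD4 cells. The Lars2 and Rn45s share is argued against as the source, since ISP had the highest count without the libraries over 7% (3760, next DP at 2876) and with the share as a covariate (4288, next CD4 at 2099). Malat1 rose in cKO ISP and input libraries, and RNA quality other than this share was not tested and stays open. DP cells mixed into the cKO sort would dilute ISP transcripts, but abundant DP genes implied a median share of 4.69% (quartiles 0.729% and 15.5%, 21 genes). That is far under the 50% that the 825 genes at least 2-fold lower would need. The 1495 higher genes are not covered, since a smaller share could raise genes high in DP cells. Rag1, Fas and Btg1 implied 15.5%, 23.4% and 42.5%, while Cd4 implied 0.863% and Ccr9, Cd52, F13a1, Sepp1 and Slc7a11 implied negative shares. Genotype remains open, with 84.2% of the genes called in ISP cells moving the same way in the input libraries.

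Dendritic cell markers were lower in cKO ISP cells, which may come from fewer dendritic cells in that sort. A second list of 26 dendritic cell genes was written before its values were seen. Of 18 tested in both experiments, 16 were lower in the cKO in both ISP cells and input, 10 were called lower in ISP cells and 7 in the input, and Cst3 and Tlr7 were the exceptions. Of the list, 7 exceeded 10 CPM in WT DN or DP cells, so not all are specific. Lower expression in the T cells themselves was not tested and stays open.

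In cKO DP cells the genes lower were longer than others, which library quality could produce. Within WT alone, DP replicate 3, with a Lars2 and Rn45s share of 6.41%, differed from replicates 1 and 2 by a Spearman correlation of −0.44 between log2 ratio and transcript length (11390 genes, 96.2% of those tested, with a length). Of the 349 genes called lower in cKO DP cells, 170 were lower in that WT library too, against 5169 of all 11841 genes. These shares lie close together. That library is also among the WT libraries behind the calls, which makes a gene low in it less likely to be called. The count therefore decides nothing here. With the share as a covariate the correlation in the DP knockout comparison went from −0.23 to 0.02. It went from −0.16 to 0.04 in ISP and from 0.25 to 0.09 in DN cells. In CD4 cells it went from −0.04 to 0.22 and in CD8 cells from −0.03 to 0.24. As the covariate removed a length trend in some subsets and gave one in others, its effect in DP cells does not settle the source. Brd4 is another matter: with the covariate it stayed lower (−1.40 ± 0.35, adjusted p = 0.0119, range over its alternatives 0.000345 to 0.158), which argues against this share as the whole reason for its fall. Malat1 was also higher in cKO than in WT DP libraries, and library quality other than this share was not tested.

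Other splits of the libraries were counted for each comparison of 3 against 3, where 10 splits are too few for a share under 0.05. The real split had the most genes in each. The counts of the real split and of the highest other were 120 and 1 in DN, 3145 and 17 in ISP, 685 and 1 in DP, 695 and 0 in CD4, and 599 and 0 in CD8 cells. In DN cells, where the numbers were taken to pair the libraries, the 3 other splits that part every pair thus gave at most 1. For WT ISP against DN, DP against ISP, CD4 against DP, CD8 against DP and CD4 against CD8 cells they were 2984, 6893, 5460, 5666 and 1731, with 0 for the highest other of each by edgeR. The mean over 5 subsets, 3407 genes, was reached by 1 of 100 groupings, the real one, and the highest other called 301. These groupings drew labels in each subset separately. Libraries of 1 genotype and number correlated between some subsets, so chance is excluded only if libraries of different subsets are independent. The 254 genes highest in WT ISP cells were reached by 6 of 100 groupings of the 9 libraries, the highest other giving 1309. Of the 5 others, 4 put the 3 libraries of another subset in the place of the ISP libraries (3 DP, 1 DN), and 1 left the ISP libraries in place and mixed the others, giving 312. This share alone does not exclude chance. In 5 simulations without differences the count was 0. These gave each gene 1 mean in all groups, so a count near 0 was fixed in advance and says nothing on chance here.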

How the results depend on the processing

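Tests chosen only after the results were seen were those with the Lars2 and Rn45s share as a covariate, those without the 3 libraries over 7% and the block over the subsets.

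With RLE size factors every count of genes stayed within 1.5 times, Brd4 kept its direction and side of the threshold in every comparison, and 240 list comparisons were called against 241. Without a filter on low counts the counts of genes and Brd4 did so too, except for cultured DP cells, cKO against WT, where 1217 genes were called against 799 and Brd4 passed the threshold (−0.70, adjusted p = 0.0301, range over its alternatives 0.0219 to 0.767), and for Brd4 in DN cells, which turned from −0.00 to 0.0203. DESeq2 called 355 genes in DN, 1162 in DP and 919 in CD8 cells, and 1912 for a difference between subsets. A fit of the compared groups alone called 0 genes in DN cells (edgeR, with 979 of 11106 at an unadjusted p under 0.05), 647 in ISP, 1775 in CD4 and 266 in CD8 cells, 1475 for WT ISP against DN and 3688 for WT CD4 against CD8, and turned Brd4 in DN cells to 0.0191. Such a fit has fewer samples to estimate the spread, and beyond that the cause was not tested. With all 38 libraries in 1 fit the counts were 1395 in the input, 186 for cultured DP against cultured ISP cells and 510 for cultured DP cells, cKO against WT. By camera with an estimated correlation 38 list comparisons were called, and by fry 263.

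With the Lars2 and Rn45s share as a covariate, 422 genes were called in DN, 1205 in DP, 2099 in CD4 and 1604 in CD8 cells, 2700 for the ISP difference, 2661 for a difference between subsets, 4858 for WT ISP against DN and 3232 for WT CD4 against CD8. Brd4 turned from −0.12 to 0.37 in CD4 cells, and its mean of −0.32 lost the call (adjusted p = 0.112, range over its alternatives 0.00498 to 0.112). Without the libraries over 7%, the counts were 2876 in DP and 1345 in CD4 cells, 2064 for the ISP difference, 2608 for a difference between subsets, 4740 for WT ISP against DN and 3031 for WT CD4 against CD8. The cause was not tested.

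The replicate number as a block gave 49 genes in DN cells, 607 for a difference between subsets and 710 for cultured DP against cultured ISP cells, and turned Brd4 in DN cells to 0.17. Counts within 1.5 times were 2972 in ISP, 651 in DP, 542 in CD4 and 441 in CD8 cells. Outside DN cells the numbers were not taken to pair the WT and cKO libraries of a subset, whose deviations correlated from −0.13 to 0.26. Over 0.1 were 6 of the 15 pairs, 3 of these in DN cells. Between subsets, all 3 pairs were over 0.1 for DN and ISP cKO libraries (0.258, 0.421 and 0.579) and for DN and DP WT libraries (0.288, 0.267 and 0.654). With libraries of 1 genotype and number over the subsets as a block, the F test called 861 genes and the ISP difference 1384, and the 6 named genes kept direction and call. The 6 pairs of cKO culture libraries had 0.0878 to 0.145. With 2 libraries per group the deviations mirror each other, so replicates 1 and 2 give the same value and are not separate evidence. For the input and for cultured DP cells, cKO against WT, there was 1 WT library. No paired analysis was possible because of that in these 2 comparisons.

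Leaving out each library in turn gave 17 to 144 genes in DN, 2201 to 3703 in ISP, 249 to 804 in DP, 351 to 563 in CD4 and 288 to 427 in CD8 cells. It gave 3074 to 4017 for the mean, 771 to 2127 for the ISP difference and 612 to 1190 for a difference between subsets. WT ISP against DN had 2240 to 3091, DP against ISP 6209 to 6840, CD4 against DP 4763 to 5089, CD8 against DP 5032 to 5273, CD4 against CD8 1171 to 1459, and genes highest in ISP cells 217 to 280. In culture the input had 1106 to 1265, cells still ISP 3383 to 4774, cells that became DP 4299 to 4646, cultured DP against ISP cells 120 to 566 and cultured DP cells, cKO against WT, 266 to 340. Where 1 library of a group was left, it was assumed to vary like the other groups. Brd4 ranged from −0.44 to 0.33 in DN, −0.97 to −0.13 in ISP, −2.35 to −1.55 in DP, −0.15 to −0.03 in CD4 and −0.75 to −0.21 in CD8 cells, −0.74 to −0.56 for the mean, −0.54 to −0.49 in the input and −1.05 to −0.42 in cultured DP cells. Its call ended without any 1 of 5 libraries in DP cells and of 15 for the mean. In DN cells it was 0.23 without WT replicate 1, 0.33 without WT replicate 2 and 0.33 without cKO replicate 3.

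Brd4 apart, whose changes are given above, all 136 values of named genes with a test kept direction and call with RLE size factors, with no filter and by DESeq2, and the 104 from libraries taken from the thymus did so with the covariate and without the libraries over 7%. In the fit of compared groups alone 81 kept them and 6 lost the call, and with the block 119 kept them and 1, Ifit1 in ISP cells, lost the call. With all 38 libraries 31 kept them and Top2a for cultured DP against ISP cells lost the call. Of these values with 1 library left out, 1126 kept direction and call and 2 lost the call. As genes whose call no left-out library ended were preferred for naming, this count follows from that choice and says nothing on genes in general. Of 29 values from 1 WT library against 1, 6 moved with total-count scaling by more than their counting interval. Depth limits the genes of low count, since no count in a library allows up to 0.385 CPM.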

Other observations

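Of the tests here, that of the direction of the ISP difference was chosen only after the result was seen.

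The interferon response gene Ifit1 was uneven between libraries of a group. In ISP cKO cells Ifit1 was at 53.95, 107 and 4.81 CPM in the 3 libraries and in ISP WT cells at 4.48, 2.62 and 17.9 CPM. In the cKO input it was at 68.5 and 15.9 CPM and in the cKO cells that became DP at 1.68 and 0.354 CPM. Hist1h2bc varied less, with 15.6, 11.4 and 18.2 CPM in ISP WT and 219, 139 and 255 CPM in ISP cKO libraries.

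All libraries carried transcripts of the Y chromosome gene Ddx3y, with 421 to 1883 counts each, and 0 to 9 counts of Xist.

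The differences between cKO and WT ISP cells ran partly in the direction of the step from ISP to DP. Across 11247 genes, the input difference correlated with the WT step from ISP to DP measured in other libraries (r = 0.41; genes are not independent replicates). Of 1925 genes called in both, 1790 went the same way. A candidate explanation was that cKO ISP cells were further along towards DP. The gene lists do not decide whether that is the whole explanation. In the WT step 27 of 30 mitosis genes fell, while edgeR called no mitosis gene in cKO ISP cells taken from the thymus. In the input, with its lone WT library, the few mitosis genes called were higher in the cKO, against the WT step. The fall of the mitosis list that this explanation predicted was thus not seen. All 30 DNA replication genes fell in the WT step too, and edgeR called part of that list lower in these cKO ISP cells. In culture most DNA replication genes fell in cells still ISP, and mitosis genes were lower in cultured DP than in cultured ISP cells. Mitosis genes that did not fall therefore do not exclude cKO ISP cells that were part of the way along. A loss of MYC-driven growth that DP cells also show could give the same correlation, and was not tested.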
